A study of Danio rerio with 11 samples.

How the data were processed

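The deposited files hold 1 FPKM value per gene and library, made by the authors. Per the submitters' processing notes, reads were aligned to GRCz10 with HISAT2 2.1.0 and counted with HTSeq 0.6.0, and the counts were divided by gene length and library total. The annotation release, gene lengths, strand setting and counting mode were not given in the sources used here, so overlapping and antisense genes cannot be separated, and values of near-identical copies such as crystallin, heat shock and hemoglobin genes are uncertain. Per the labels' protocols, RNA from snap-frozen AB larvae was extracted with Trizol and 3 µg went into NEBNext Ultra libraries read as 150 bp pairs on an Illumina instrument.

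The design, fixed before the data were examined, had assumed counts. Because the values are FPKM, the test was changed to limma (3.58.1, R 4.3.3) on log2(FPKM / TMM factor + 0.1), with variances moderated along a trend on mean expression and p-values adjusted by the Benjamini-Hochberg method within each comparison. The comparisons, groups, gene lists, panel and threshold of 0.05 were chosen before the data were examined. The choice of limma, its trend and the pseudocount of 0.1 came after the unit was known. All 11 libraries entered 1 fit with a mean per group (7 residual and 5.2 prior degrees of freedom). The groups were control (2 libraries), DBP (3), DiBP (3) and the combined exposure (3). The series describes triplicates, and the third control was not analysed here.

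Whole read numbers behind the FPKM values were recovered for 100% of genes (within 1e-06 reads plus the rounding of each value, with library totals within 0.00442 of a whole number), because each value is a whole number of reads times a constant per gene and library. The step was checked on 5966 simulated genes, of which 99.586% of values came back exactly. Recovered depth was 14703472 and 15061899 reads for the controls, 14969848, 14000430 and 13396589 for DBP, 14690854, 15381114 and 15046503 for DiBP, and 14008094, 14406045 and 14307707 for the combined exposure. These reads were used only for the low-value filter, the scaling factors and 1 alternative test. A gene was tested if it had the CPM of 10 reads in at least 2 libraries and a total of 15 or more, which left out 8160 genes and kept 19465. TMM factors (30% and 5% trimmed) ran from 0.9346 to 1.1012. Replicate numbers were not used as pairs: profiles that shared a number correlated by -0.034 to 0.136, and 6 of 11 libraries correlated best with their own number.

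There were 7 comparisons: each exposure with control, DBP with DiBP, the combined exposure with each isomer, and the interaction (combined minus DBP minus DiBP plus control). The main test was tested on simulated data of the same layout. For DBP against control it called 20.9%, 64.2% and 93.9% of genes changed by 1.5, 2 and 4 times, and 6 unchanged genes. For the interaction it called 4.5%, 31.3% and 80.3%, and 8 unchanged genes. Those simulated genes varied independently. Where the deviations of genes within each group were kept together, unchanged groups gave a median of 0 calls but up to 10439 for DBP against control and 7670 for the interaction, and as many as observed in 22 and 5 of 100 simulations.

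Gene lists, 36 in all, were written down before the data were examined and tested with camera from limma (preset correlation 0.01, lists of 5 or more tested genes, adjusted within each comparison). Of 1677 gene names outside the ribosomal list, 1585 were found. As a stricter form, camera was also run with the correlation estimated from the residuals. Counts of called members are given after adjustment over all genes and after adjustment over the list alone.

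Genes named in the text follow a rule fixed beforehand. For each comparison these are the 8 largest rises and 8 largest falls among called genes with a symbol, groups that do not overlap and a mean of 20 or more reads, then up to 4 members with the smallest p of each list that was called or had 3 or more called members. A panel of known phthalate targets is named in the comparisons with control, and so are up to 10 genes called the same way in all 3. The clock genes were also grouped by peak time, after the values were seen.

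Alternatives tried were RLE scaling, values as deposited, no filter, a mean CPM of 5 or more, pseudocounts of 0.01 and 1, a 2-fold threshold, voom on the recovered reads, replicate number as a block, only the groups compared, each library left out in turn, and both libraries that stood apart left out. Chosen after seeing the data were values as deposited, both pseudocounts, voom, leaving out both apart libraries, the filter alternatives for gene lists, and every alternative for the overlap except the 2-fold threshold. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15 with NumPy 2.4.6. Results for 3 genes, 1 of them in the phthalate panel, are not reported here.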

Results

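RNA was sequenced from zebrafish larvae collected 120 h after fertilization, the offspring of adults kept for 30 days with dibutyl phthalate (DBP), with diisobutyl phthalate (DiBP), with both, or with neither. There were 2 control libraries and 3 libraries each for DBP, DiBP and the combined exposure, 11 in all, with recovered totals of 13396589 to 15381114 reads per library. After a low-value filter left out 8160 genes, 19465 were tested. Changes below are differences on the log2(FPKM + 0.1) scale with their standard errors, for which limma gave the adjusted p, and this scale understates the change of genes with low values. Gene symbols are printed as the gene table gives them, with the Ensembl gene ID at first mention, because many carry the human symbol and some are shared by paralogues. Nothing in the labels says whether the libraries come from separate clutches or tanks, so the p-values measure spread between these samples, which may be technical. Exposure doses were not given in the sources used here.

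Exposed groups, unlike controls, lay separately in a principal component plot, and 2 libraries stood apart. Components 1 and 2 held 34.9% and 21.3% of the variance. DiBP libraries sat at 41.5 to 44.9 on component 1, DBP libraries at 10.1 to 17.2, combined libraries at -29.4 to -24.1 and control libraries at -71.2 (library 1) and -21.9 (library 2). The control libraries differed by 2-fold or more in 2338 genes (12.01% of those tested), and combined library 3 differed from libraries 1 and 2 of its group in 1236 and 1219 genes (6.35% and 6.26%), where other pairs of replicates differed in 362 to 563. Control library 1 had the lowest levels of the muscle, skin and exocrine pancreas gene lists and the highest of the lens and mitochondrial lists, so values for those lists are given with and without it.

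**Figure D1:**
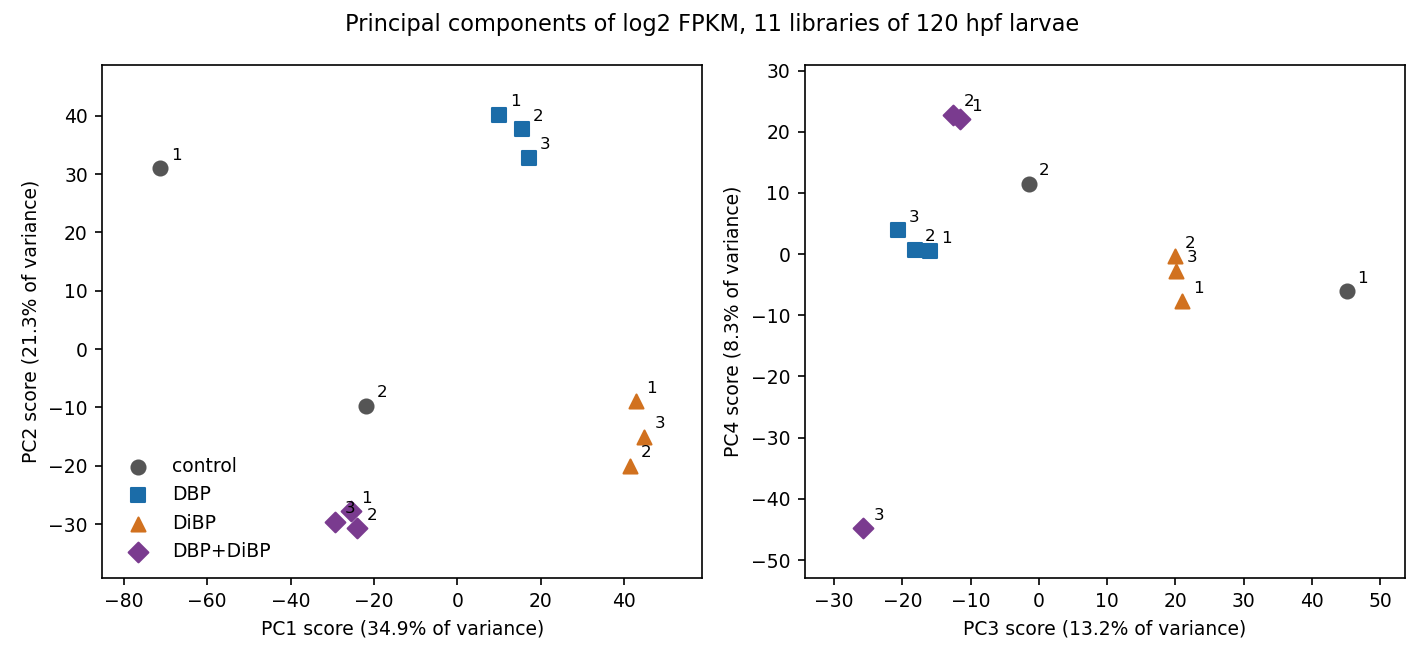
Scores of the 11 libraries on components 1 and 2 (left) and 3 and 4 (right) of log2(FPKM + 0.1), in units of log2 summed over genes, with 1 point per library, colored by group and numbered by replicate. Control library 1 lies at -71.2 on component 1 against -21.9 for control library 2, and combined library 3 lies at -44.8 on component 4 against 22.1 and 22.8 for the other two combined libraries.

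Against the controls, 2946 genes (15.1% of those tested) differed in DBP offspring, 5807 (29.8%) in DiBP offspring and 671 (3.4%) in offspring of the combined exposure, at an adjusted p under 0.05. Genes higher and lower numbered 1871 and 1075 for DBP, 3079 and 2728 for DiBP and 342 and 329 for the combined exposure. Calls with changes of 2-fold or more were 1074, 1975 and 267. In 100 simulations of unchanged groups, which kept the joint deviations of genes within each group, the median number of calls was 0. As many calls as observed arose in 22 (DBP), 13 (DiBP) and 32 (combined) of the 100, with up to 10439, 10442 and 10651 calls. With only 2 controls, these simulations cannot judge the counts. A median absolute change as large as observed arose in 14, 2 and 33. For DBP against DiBP, combined against DBP, combined against DiBP and the interaction, 1, 7, 5 and 5 of the 100 gave as many calls, and 0 as large a median absolute change. With values scaled as deposited, without the correction for composition, the share that was higher moved from 63.5% to 43.2% for DBP and from 51% to 70.4% for the combined exposure, so the split between higher and lower genes depended on the scaling. That scaling moved the median of all genes by 0.15 for the combined exposure against DBP, 0.11 against DiBP and 0.20 for the interaction, and by less than 0.1 elsewhere.

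**Figure D2:**
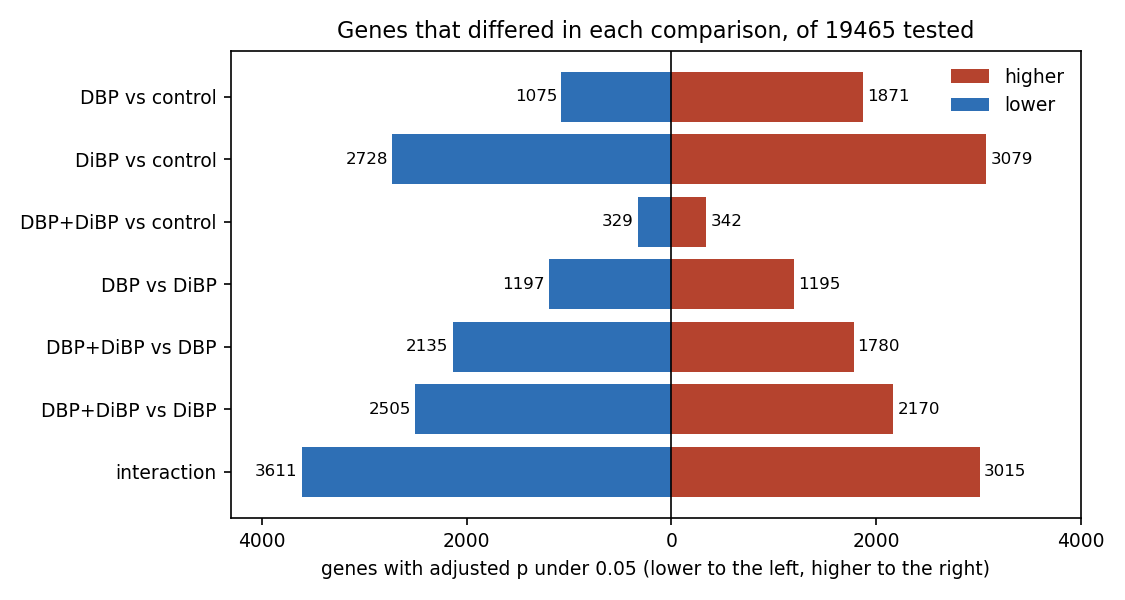
Genes with an adjusted p under 0.05 in each of the 7 comparisons, with bars for higher genes to the right of 0 and for lower genes to the left (number of genes). The comparison of DiBP with control has 3079 higher and 2728 lower genes, and that of the combined exposure with control has 342 and 329.

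DBP and control. Genes of the intestine rose in DBP offspring, with 3 libraries against 2. The fatty acid binding protein FABP1 (ENSDARG00000059227, 3.65 ± 0.40, adjusted p = 2.32e-04) went from a mean of 17.8 to 179 FPKM, and the apolipoproteins apoa4b.1 (ENSDARG00000040298, 2.37 ± 0.16, adjusted p = 1.67e-05) and apoa4b.2 (ENSDARG00000020866, 2.82 ± 0.27), which are made with lipoproteins in the intestine, rose with it. Also higher were chia.3 (ENSDARG00000009612, 3.25 ± 0.33), a chitinase, and DGAT2 (ENSDARG00000018846, 2.69 ± 0.28), which makes triglycerides. In the intestine list 24 of 37 rose and 0 fell (26 and 0 adjusted over the list alone). The median was 1.34 (adjusted p = 9.76e-15, or 0.0963 with estimated correlation). In the exocrine pancreas list 16 of 22 rose and 0 fell (18 and 0 over the list alone), led by the protease gene prss59.1 (ENSDARG00000079274, 1.82 ± 0.25) and the carboxypeptidase genes CPA1 (ENSDARG00000021339, 1.56 ± 0.23) and CPA1 (ENSDARG00000030915, 1.61 ± 0.24). The median was 1.15 (adjusted p = 4.16e-08, or 0.368 with estimated correlation). The pancreas median was 0.57 without control library 1 and 1.80 without control library 2.

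Some metabolic lists rose as well. Among nuclear genes of oxidative phosphorylation 49 of 82 rose and 0 fell (64 and 1 over the list alone), with NDUFA10 (ENSDARG00000013333, 0.84 ± 0.10) and NDUFS8 (ENSDARG00000051986, 0.58 ± 0.10) of complex I and atp5mf (ENSDARG00000037867, 0.68 ± 0.09) of the ATP synthase as examples. The median was 0.46 (adjusted p = 2.00e-17, or 0.29 with estimated correlation). It was 0.30 without control library 1. In the list of fatty acid oxidation and PPAR genes 14 of 44 rose and 0 fell (18 and 2 over the list alone), including the acyl-CoA dehydrogenases ACADVL (ENSDARG00000016687, 1.11 ± 0.10, adjusted p = 8.35e-05) and ACADM (ENSDARG00000038900, 0.60 ± 0.09) and the fatty acid transporter CD36 (ENSDARG00000032639, 1.64 ± 0.18). The median was 0.24 (adjusted p = 1.07e-05, or 0.159 with estimated correlation). Ribosomal protein genes (4 of 83 higher, 0 lower, 0 and 0 over the list alone, median 0.36, adjusted p = 4.47e-09, or 0.495 with estimated correlation) had a median of 0.10 without control library 1 (adjusted p = 0.0343) and 0.61 without control library 2. Sterol and fatty acid synthesis genes moved less: 5 of 33 rose and 0 fell (5 and 0 over the list alone). The median was 0.24 (adjusted p = 0.0185, or 0.166 with estimated correlation). That call was lost without either control library (medians 0.07 and 0.28, adjusted p = 0.0585 and 0.0906). Of the 43 liver genes, 5 rose and 2 fell (5 and 2 over the list alone), with a median of -0.05 and a mean of 0.12 (adjusted p = 0.685). Examples are apoa1a (ENSDARG00000012076, 2.09 ± 0.24) and apobb.1 (ENSDARG00000022767, 1.78 ± 0.27) higher and the coagulation factor gene F10 (ENSDARG00000088581, -1.31 ± 0.13) lower. In the list of mitochondrially encoded genes 0 of 13 rose and 2 fell (0 and 2 over the list alone), with mt-nd4l (ENSDARG00000063916, -0.95 ± 0.16) called, and the list was not called without control library 1 (median -0.12, adjusted p = 0.193). The median was -0.38 (adjusted p = 0.00581, or 0.495 with estimated correlation).

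Cell cycle genes fell in DBP offspring: 0 of 84 rose and 24 fell (0 and 30 over the list alone). The median was -0.40 (adjusted p = 5.67e-08, or 0.166 with estimated correlation). The replication helicase gene MCM7 (ENSDARG00000101180, -1.29 ± 0.20, adjusted p = 0.00194), TOP2A (ENSDARG00000024488, -1.0 ± 0.18) for the topoisomerase of dividing cells, and KIF23 (ENSDARG00000014943, -0.92 ± 0.15) and PRC1 (ENSDARG00000100918, -1.06 ± 0.19) of cytokinesis are examples. Genes for DNA methylation and histone marks were split: 6 of 56 rose and 5 fell (6 and 5 over the list alone), with mbd3b (ENSDARG00000061810, -0.50 ± 0.09), dnmt3ba (ENSDARG00000052402, -0.52 ± 0.10) and EED (ENSDARG00000099640, 0.67 ± 0.13) among those called. The median was -0.17 (adjusted p = 0.0397, or 0.166 with estimated correlation). The call for that list was lost without control library 1, control library 2 or DBP library 1 (adjusted p = 0.104, 0.117 and 0.0774).

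Photoreceptor and visual cycle genes changed in both directions in DBP offspring. The opsin kinase GRK7 (ENSDARG00000020602, 1.89 ± 0.11, adjusted p = 7.74e-06), the arrestins ARR3 (ENSDARG00000056511, 1.76 ± 0.14, adjusted p = 3.40e-05) and ARR3 (ENSDARG00000098475, 1.34 ± 0.14) and the phosphodiesterase PDE6C (ENSDARG00000100397, 1.55 ± 0.15) rose, while GUCA1A (ENSDARG00000101567, -4.09 ± 0.60), an activator of guanylate cyclase, fell from 2.35 to 0.0427 FPKM. In the photoreceptor and visual cycle list 16 of 63 rose and 5 fell (21 and 6 over the list alone). The median was 0.29 (adjusted p = 2.99e-04, or 0.423 with estimated correlation). Its median was 0.17 without control library 1 and 0.46 without control library 2. Among clock genes, BHLHE40 (ENSDARG00000004060, 1.62 ± 0.14, adjusted p = 7.30e-05) and PER1 (ENSDARG00000012499, 2.33 ± 0.32) rose and cry3b (ENSDARG00000091131, -0.88 ± 0.10) fell, with 9 of 54 higher and 4 lower (11 and 6 over the list alone, adjusted p = 0.553).

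Muscle, skin and lens lists also differed from the controls, and these are the lists in which control library 1 stood apart. In the muscle list 31 of 65 rose and 0 fell (51 and 1 over the list alone). The median was 1.21 (adjusted p = 2.85e-12, or 0.462 with estimated correlation). In the skin list 20 of 39 rose and 0 fell (28 and 0 over the list alone). The median was 0.85 (adjusted p = 1.94e-11, or 0.398 with estimated correlation). In the lens list 0 of 53 rose and 10 fell (0 and 30 over the list alone). The median was -1.48 (adjusted p = 3.12e-09, or 0.462 with estimated correlation). Without control library 1 the medians became 0.33, 0.40 and -0.13, with adjusted p = 5.53e-06, 6.78e-07 and 0.242, and without control library 2 the muscle and lens medians became 1.96 and -2.79. The myosin gene myhz2 (ENSDARG00000012944, 1.81 ± 0.32) had a change of 1.03 without control library 1, and CRYBB1 (ENSDARG00000068507, -1.5 ± 0.39), a crystallin of the lens, had -0.57 without control library 1 and -2.44 without control library 2. The skin genes epcam (ENSDARG00000040534, 1.16 ± 0.10, adjusted p = 8.35e-05), krt4 (ENSDARG00000017624, 1.6 ± 0.23) and agr1 (ENSDARG00000060682, 2.29 ± 0.30) and the calcium-store gene SRL (ENSDARG00000112959, 1.68 ± 0.18) of muscle kept their calls without either library.

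Defense and stress genes changed in part. In the neutrophil and macrophage list 11 of 38 rose and 0 fell (12 and 0 over the list alone), with the neutrophil protease npsn (ENSDARG00000010423, 2.21 ± 0.26), nccrp1 (ENSDARG00000035326, 0.79 ± 0.12) and the transcription factor CEBPB (ENSDARG00000042725, 1.2 ± 0.14). The median was 0.44 (adjusted p = 5.36e-04, or 0.195 with estimated correlation). It was 0.25 without control library 1. The feedback regulators SOCS3 (ENSDARG00000025428, 0.97 ± 0.08, adjusted p = 6.37e-05) and nfkbiaa (ENSDARG00000005481, 0.76 ± 0.14), the stress-responsive GADD45B (ENSDARG00000027744, 0.99 ± 0.09, adjusted p = 1.12e-04) and the survival gene mcl1a (ENSDARG00000009779, 0.69 ± 0.10) rose, as did ern1 (ENSDARG00000013997, 1.52 ± 0.12, adjusted p = 3.40e-05), a sensor of unfolded protein in the endoplasmic reticulum. In the xenobiotic metabolism list 10 of 32 rose and 1 fell (15 and 1 over the list alone), including the export pump abcc2 (ENSDARG00000014031, 1.05 ± 0.15) and cyp2n13 (ENSDARG00000042953, 0.78 ± 0.14). The median was 0.38 (adjusted p = 9.01e-04, or 0.293 with estimated correlation). Without control library 1, 5 rose and 0 fell. In the antioxidant list 8 of 35 rose and 1 fell (10 and 3 over the list alone), led by the metallothionein MT1X (ENSDARG00000041623, 1.39 ± 0.15, adjusted p = 1.92e-04) and gpx4a (ENSDARG00000068478, 1.13 ± 0.17). The median was 0.21 (adjusted p = 0.0103, or 0.274 with estimated correlation). It was 0.10 without control library 1. The thyroid hormone receptor gene THRA (ENSDARG00000000151, 1.0 ± 0.12) rose, but the thyroid list did not move as a whole, with 3 of 19 higher and 2 lower (4 and 2 over the list alone, adjusted p = 0.439). Glucose and fasting genes (15 of 53 higher, 3 lower, 19 and 3 over the list alone, median 0.37, adjusted p = 0.00277, or 0.462 with estimated correlation) and extracellular matrix genes (15 of 54 higher, 0 lower, 19 and 0 over the list alone, median 0.34, adjusted p = 8.12e-04, or 0.495 with estimated correlation) were higher, and both calls were lost without control library 1 (adjusted p = 0.115 and 0.193). Unchanged groups gave as large a median in 5 or more of 100 simulations for 7 of the 18 lists called with DBP: lens (31), extracellular matrix (30), muscle (19), ribosomal (15), glucose (14), mitochondrial (12) and skin (9).

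Of the genes chosen beforehand as known phthalate targets, the metallothionein MT1X rose in DBP offspring, as above, and kept its call with every alternative. ESR1 (ENSDARG00000004111, -0.81 ± 0.24, adjusted p = 0.0429), an estrogen receptor gene, and DNMT1 (ENSDARG00000030756, -0.53 ± 0.12, adjusted p = 0.0129), the maintenance DNA methyltransferase, were lower, and SOD1 (ENSDARG00000043848, 0.45 ± 0.11, adjusted p = 0.0193) was higher, and each of these 3 calls was lost when single libraries were left out, among them control library 1 for ESR1 (adjusted p = 0.109) and DNMT1 (adjusted p = 0.0777) and control library 2 for SOD1 (adjusted p = 0.0556). The yolk protein gene vtg1 (ENSDARG00000092233, -0.12 ± 0.28), the dioxin-responsive CYP1A1 (ENSDARG00000098315, -0.38 ± 0.30), the steroid carrier STAR (ENSDARG00000006137, 0.38 ± 0.23) and the cytokine il1b (ENSDARG00000098700, -0.91 ± 0.29) did not pass the test. Genes for aromatase, the androgen receptor and PPAR alpha named in that panel held too few reads to be tested. The count of 2946 genes rested on both groups: it was 6061 without control library 2, 1734, 1556 and 1622 without DBP libraries 1, 2 and 3, and 912 when the 5 libraries compared were fitted alone.

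DiBP and control. Clock genes were among the largest changes in DiBP offspring, with 3 libraries against 2. The repressor NR1D1 (ENSDARG00000033160, 6.01 ± 0.84, adjusted p = 4.16e-04) went from 1.28 to 89 FPKM, and PER1 (5.0 ± 0.32, adjusted p = 2.56e-06), PER1 (ENSDARG00000056885, 4.31 ± 0.54), ciarta (ENSDARG00000058094, 4.01 ± 0.38) and CRY2 (ENSDARG00000102403, 3.14 ± 0.15) rose, while rorcb (ENSDARG00000017780, -3.76 ± 0.68), nfil3-5 (ENSDARG00000094965, -3.34 ± 0.65) and cry3b (-2.50 ± 0.10) fell. In the clock and light list 25 of 54 rose and 8 fell (25 and 10 over the list alone). The median was 0.41 (adjusted p = 0.00868, or 0.131 with estimated correlation). Outside the list, nub1 (ENSDARG00000061417, 3.62 ± 0.39), a regulator of protein turnover, and lmod3 (ENSDARG00000062662, 3.43 ± 0.24), of muscle thin filaments, rose, and cbln13 (ENSDARG00000026904, -4.46 ± 0.31) and cyp2aa11 (ENSDARG00000103456, -3.02 ± 0.31) fell.

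Cell cycle genes fell in DiBP offspring: 1 of 84 rose and 47 fell (2 and 55 over the list alone). The median was -0.73 (adjusted p = 5.43e-12, or 0.071 with estimated correlation). RRM2 (ENSDARG00000078069, -1.96 ± 0.14, adjusted p = 4.78e-06), which makes deoxynucleotides, TOP2A (-1.75 ± 0.18), the mitotic kinase AURKB (ENSDARG00000037640, -1.34 ± 0.14) and the cyclin CCNA2 (ENSDARG00000011094, -1.4 ± 0.15) all fell. All 4 were also lower with DiBP than with DBP in the test between the isomers. Mean levels of the list were 0.41, 0.07, 0 and -0.3 in controls, both, DBP and DiBP, and clock phase (morning minus evening) -1.83, -1.19, -0.2 and 2.53, the same order. That order rests on combined library 3 (0.45), since combined libraries 1 and 2 lay at -2.12 and -1.92, and no relation was tested.

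Lipid synthesis genes rose in DiBP offspring: 11 of 33 rose and 0 fell (11 and 0 over the list alone), among them FASN (ENSDARG00000087657, 0.86 ± 0.09, adjusted p = 7.38e-05) and ACACA (ENSDARG00000078512, 1.07 ± 0.12), the enzymes that make fatty acids from acetyl-CoA, and the sterol enzyme EBP (ENSDARG00000046098, 1.04 ± 0.20). The median was 0.53 (adjusted p = 9.64e-04, or 0.071 with estimated correlation). Oxidation genes rose beside them: 16 of 44 rose and 2 fell (17 and 3 over the list alone), with ACADVL (0.83 ± 0.10), CD36 (1.41 ± 0.18) and the lipase LPL (ENSDARG00000087697, 0.84 ± 0.09). The median was 0.22 (adjusted p = 0.00304, or 0.234 with estimated correlation). Nuclear genes of oxidative phosphorylation rose: 40 of 82 rose and 2 fell (56 and 4 over the list alone). The median was 0.38 (adjusted p = 2.10e-09, or 0.486 with estimated correlation). It was 0.19 without control library 1. In the mitochondrially encoded list 0 of 13 rose and 8 fell (0 and 9 over the list alone). The median was -0.55 (adjusted p = 9.64e-04, or 0.492 with estimated correlation). It was -0.30 without that library. In the glucose and fasting list 24 of 53 rose and 3 fell (25 and 4 over the list alone), with fbp1a (ENSDARG00000021366, 0.89 ± 0.11) of gluconeogenesis and the hexokinase HK2 (ENSDARG00000101482, 1.65 ± 0.23) as examples. The median was 0.53 (adjusted p = 9.72e-04, or 0.486 with estimated correlation). It was 0.82 without control library 2. In the intestine list 22 of 37 rose and 0 fell (22 and 0 over the list alone), where the peptidases ANPEP (ENSDARG00000103878, 1.96 ± 0.23) and mep1a.1 (ENSDARG00000029747, 1.68 ± 0.17) and the lipid carrier FABP2 (ENSDARG00000006427, 1.75 ± 0.25) were among the called genes. The median was 0.90 (adjusted p = 7.03e-07, or 0.188 with estimated correlation).

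Photoreceptor genes went both ways in DiBP offspring, with 15 of 63 higher and 16 lower (18 and 18 over the list alone, adjusted p = 0.957). GRK7 (2.74 ± 0.11, adjusted p = 3.49e-08), ARR3 (2.68 ± 0.14) and PDE6C (2.59 ± 0.15) rose, and GUCA1A (-3.26 ± 0.60) and LRAT (ENSDARG00000037278, -3.59 ± 0.35, adjusted p = 4.81e-05), the enzyme that esterifies retinol, fell. In the lens list 0 of 53 rose and 33 fell (0 and 36 over the list alone). The median was -2.10 (adjusted p = 2.36e-10, or 0.486 with estimated correlation). In the muscle list 45 of 65 rose and 0 fell (51 and 0 over the list alone). The median was 1.32 (adjusted p = 1.15e-10, or 0.486 with estimated correlation). In the skin list 23 of 39 rose and 0 fell (27 and 0 over the list alone). The median was 0.80 (adjusted p = 5.37e-08, or 0.486 with estimated correlation). Without control library 1 these medians were -0.81, 0.44 and 0.33 and the calls held (adjusted p = 1.08e-07, 7.31e-08 and 5.93e-05), and without control library 2 they were -3.24, 2.25 and 1.34. Exocrine pancreas genes (4 of 22 higher, 0 lower, 2 and 0 over the list alone, median 0.55, adjusted p = 0.0323, or 0.676 with estimated correlation) had a median of -0.04 without control library 1 (adjusted p = 0.932). Ribosomal protein genes (2 of 83 higher, 0 lower, 1 and 0 over the list alone, median 0.23, adjusted p = 0.00738, or 0.816 with estimated correlation) had -0.05 without it (adjusted p = 0.273) and 0.49 without control library 2. Heart genes were higher: 8 of 31 rose and 0 fell (8 and 0 over the list alone), with atp2a2a (ENSDARG00000029439, 1.72 ± 0.18) and TNNT2 (ENSDARG00000100694, 1.21 ± 0.24). The median was 0.53 (adjusted p = 0.00304, or 0.486 with estimated correlation). It was 0.29 without control library 1. Extracellular matrix genes (17 of 54 higher, 2 lower, 17 and 2 over the list alone, median 0.37, adjusted p = 0.00313, or 0.552 with estimated correlation) were not called without control library 1 (adjusted p = 0.273). Unchanged groups gave as large a median in 5 or more of 100 simulations for 6 of the 17 lists called with DiBP: ribosomal (43), exocrine pancreas (28), extracellular matrix (28), muscle (15), skin (14) and lens (12).

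Chemical defense genes split. MT1X (1.39 ± 0.15, adjusted p = 8.55e-05) rose, and so did keap1a (ENSDARG00000016132, 1.2 ± 0.16), the sensor of the antioxidant response, and the pumps abcc2 (1.03 ± 0.15) and ABCB4 (ENSDARG00000010936, 1.46 ± 0.22), while CAT (ENSDARG00000104702, -0.79 ± 0.11), catalase, and cyp2aa4 (ENSDARG00000098803, -2.90 ± 0.32, adjusted p = 1.10e-04), a cytochrome of family 2, fell. In the antioxidant list 10 of 35 rose and 2 fell (11 and 2 over the list alone). The median was 0.24 (adjusted p = 0.00394, or 0.234 with estimated correlation). It was 0.37 without control library 2. The xenobiotic list (10 of 32 higher, 4 lower, 11 and 4 over the list alone, median 0.33, adjusted p = 0.0349, or 0.486 with estimated correlation) was not called without control library 1 or combined library 3 (adjusted p = 0.152 and 0.0541). SOCS3 (0.98 ± 0.08), CEBPB (1.18 ± 0.14) and GADD45B (0.86 ± 0.09) rose here too. Among heat shock genes, HSF2 (ENSDARG00000053097, 2.13 ± 0.15, adjusted p = 6.37e-06), a transcription factor of the family, rose and the chaperone HSPH1 (ENSDARG00000019874, -1.62 ± 0.19) fell, with 8 of 41 higher and 6 lower (8 and 6 over the list alone, adjusted p = 0.507), though the list was called higher without control library 2 (0.48, adjusted p = 0.0129). Genes of the phthalate panel that passed the test included SOD1 (0.47 ± 0.11), gpx1a (ENSDARG00000018146, 0.66 ± 0.12) and DNMT1 (-0.37 ± 0.12), whose call was lost without control library 1 (-0.17, adjusted p = 0.336). CYP1A1 (-0.36 ± 0.30), vtg1 (-0.20 ± 0.28) and ESR1 (-0.51 ± 0.24) did not pass. The count of 5807 genes was 3562 without control library 1 and 3430 when the 5 libraries compared were fitted alone. It was 8599 without control library 2, where the lone control is assumed to vary like the other groups.

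**Figure D3:**
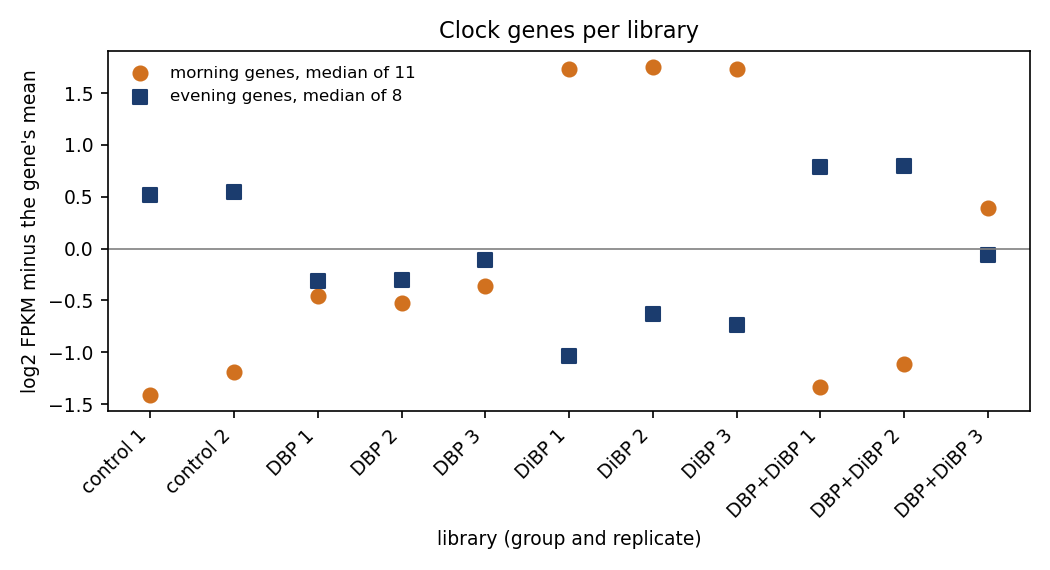
Median log2 level relative to each gene's mean, per library, of 11 clock genes that peak in the morning (circles) and 8 in the evening (squares). Each library has 1 circle and 1 square. The grouping was made after the values were seen. DiBP libraries lie at 1.73 to 1.75 for morning genes against -1.41 and -1.19 in the controls, and combined library 3 lies at 0.39 against -1.33 and -1.11 for the other two of its group.

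Combined exposure and control. Fewer genes passed the test in offspring of the combined exposure, and photoreceptor genes were among those that rose, with 3 libraries against 2. The green cone opsin opn1mw1 (ENSDARG00000097008, 1.34 ± 0.11, adjusted p = 2.00e-04), the phosphodiesterase subunit PDE6H (ENSDARG00000056791, 1.39 ± 0.12, adjusted p = 2.78e-04), rcvrna (ENSDARG00000052223, 1.82 ± 0.18, adjusted p = 7.35e-04), a recoverin, guca1aa (ENSDARG00000010454, 2.83 ± 0.31) and the photoreceptor transcription factor CRX (ENSDARG00000043483, 1.0 ± 0.12) rose, as did aanat2 (ENSDARG00000079802, 2.35 ± 0.24, adjusted p = 0.00102), the melatonin enzyme of the pineal gland. In the photoreceptor list 18 of 63 rose and 0 fell (28 and 1 over the list alone). The median was 0.42 (adjusted p = 2.37e-11, or 0.245 with estimated correlation). Heat shock genes fell: 0 of 41 rose and 11 fell (2 and 22 over the list alone), with the chaperones HSP90AA1 (ENSDARG00000024746, -3.10 ± 0.39, adjusted p = 0.00213), SERPINH1 (ENSDARG00000019949, -2.68 ± 0.36), HSPH1 (-1.44 ± 0.19) and FKBP4 (ENSDARG00000008447, -0.95 ± 0.13). The median was -0.67 (adjusted p = 7.69e-09, or 0.562 with estimated correlation). The median of that list was -0.43 without combined library 3, -1.01 without control library 1 and -0.32 without control library 2, and 7 of 100 simulations of unchanged groups gave as large a median.

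Immediate early genes fell in these larvae: 0 of 47 rose and 10 fell (0 and 16 over the list alone), including NR4A1 (ENSDARG00000000796, -0.60 ± 0.10), JUNB (ENSDARG00000104773, -0.63 ± 0.11) and IER5L (ENSDARG00000054906, -0.63 ± 0.10). The median was -0.23 (adjusted p = 7.69e-09, or 0.0691 with estimated correlation). Cell cycle genes fell too: 0 of 84 rose and 12 fell (0 and 14 over the list alone), with PCNA (ENSDARG00000054155, -0.69 ± 0.10, adjusted p = 0.00423), RRM2 (-0.88 ± 0.14) and GINS1 (ENSDARG00000007624, -0.86 ± 0.16). The median was -0.31 (adjusted p = 1.15e-09, or 0.138 with estimated correlation). Without control library 1, 6 fell. Among clock genes BHLHE40 (-1.99 ± 0.14, adjusted p = 1.32e-04) and PER3 (ENSDARG00000010519, -1.15 ± 0.17) fell and nr1d2a (ENSDARG00000003820, 0.93 ± 0.14) rose, with 5 of 54 higher and 2 lower (7 and 2 over the list alone, adjusted p = 0.444). CYP1A1 (-1.29 ± 0.30, adjusted p = 0.0368) was lower, and that call was lost without any 1 library other than control library 2 or combined library 3. For example, it was -1.28 without control library 1 (adjusted p = 0.0828), -1.17 without combined library 2 (adjusted p = 0.109) and -1.70 without combined library 3 (adjusted p = 2.56e-04). In the xenobiotic list 1 of 32 rose and 4 fell (4 and 6 over the list alone, adjusted p = 0.168), and the list was called lower without control library 1 (adjusted p = 0.0102).

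In the intestine list 5 of 37 rose and 0 fell (9 and 0 over the list alone), with chia.3 (2.02 ± 0.33) called, and the list call was lost without control library 2 or combined library 2 (adjusted p = 0.0508 and 0.111). The median was 0.30 (adjusted p = 0.00997, or 0.562 with estimated correlation). In the lens list 0 of 53 rose and 24 fell (0 and 40 over the list alone). The median was -2.06 (adjusted p = 1.04e-20, or 0.562 with estimated correlation). It was -0.68 without control library 1 and -3.28 without control library 2. The muscle list (1 of 65 higher, 0 lower, 1 and 0 over the list alone, median 0.83, adjusted p = 1.31e-09, or 0.6 with estimated correlation) had a median of -0.05 without control library 1 (adjusted p = 0.357) and 1.64 without control library 2. The skin list (4 of 39 higher, 0 lower, 13 and 0 over the list alone, median 0.32, adjusted p = 1.66e-05, or 0.6 with estimated correlation) had 0.04 without control library 1 (adjusted p = 0.965), 0.84 without control library 2 and 0.54 without combined library 3. The oxidative phosphorylation list (1 of 82 higher, 1 lower, 1 and 1 over the list alone, median 0.17, adjusted p = 9.12e-05, or 0.6 with estimated correlation) had 0.00 without control library 1 (adjusted p = 0.803) and 0.30 without control library 2. The mitochondrially encoded list was lower (0 of 13 higher, 2 lower, 0 and 8 over the list alone, median -0.47, adjusted p = 5.61e-06, or 0.562 with estimated correlation), with mt-nd4l (-1.07 ± 0.16) and MT-ND5 (ENSDARG00000063921, -0.71 ± 0.12), and their median was -0.22 without control library 1. Sterol and fatty acid synthesis genes (2 of 33 higher, 0 lower, 4 and 1 over the list alone, median 0.18, adjusted p = 0.0462, or 0.245 with estimated correlation) and heart genes (0 of 31 higher, 0 lower, 0 and 0 over the list alone, median 0.30, adjusted p = 0.0462, or 0.6 with estimated correlation) were not called with values scaled as deposited (adjusted p = 0.0683 and 0.103), nor without control library 1 (adjusted p = 0.102 and 0.923). Without combined library 1 their adjusted p was 0.0717 and 0.138, the sterol list was lost also without control library 2 (adjusted p = 0.168) and combined library 3 (adjusted p = 0.0512), and the heart list without combined library 2 (adjusted p = 0.135). Unchanged groups gave as large a median in 62 (skin), 36 (muscle), 35 (oxidative phosphorylation), 26 (heart) and 12 (lens) of 100 simulations. For exocrine pancreas genes the median (0.14) and the mean (-0.09) differed in sign (adjusted p = 0.876), and the list was called in opposite directions without control library 1 (median -0.48, adjusted p = 1.02e-06) and without control library 2 (median 0.57, adjusted p = 0.00304).

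Of the phthalate panel, MT1X (-0.05 ± 0.15), vtg1 (0.04 ± 0.28), STAR (0.00 ± 0.23), nppa (ENSDARG00000052960, 0.97 ± 0.36) and hsp70l (ENSDARG00000055723, -3.17 ± 1.08) did not pass the test in these larvae. In place of 671 genes, the 5 libraries fitted alone gave 0 in limma (1985 of 18649 at an unadjusted p under 0.05, lowest adjusted p = 0.0976). Without control library 2 the count was 4654, without combined libraries 1, 2 and 3 it was 253, 243 and 1089, and without any 1 of the DBP or DiBP libraries, which lend the fit its estimate of spread, it was 320 to 345.

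**Figure D4:**
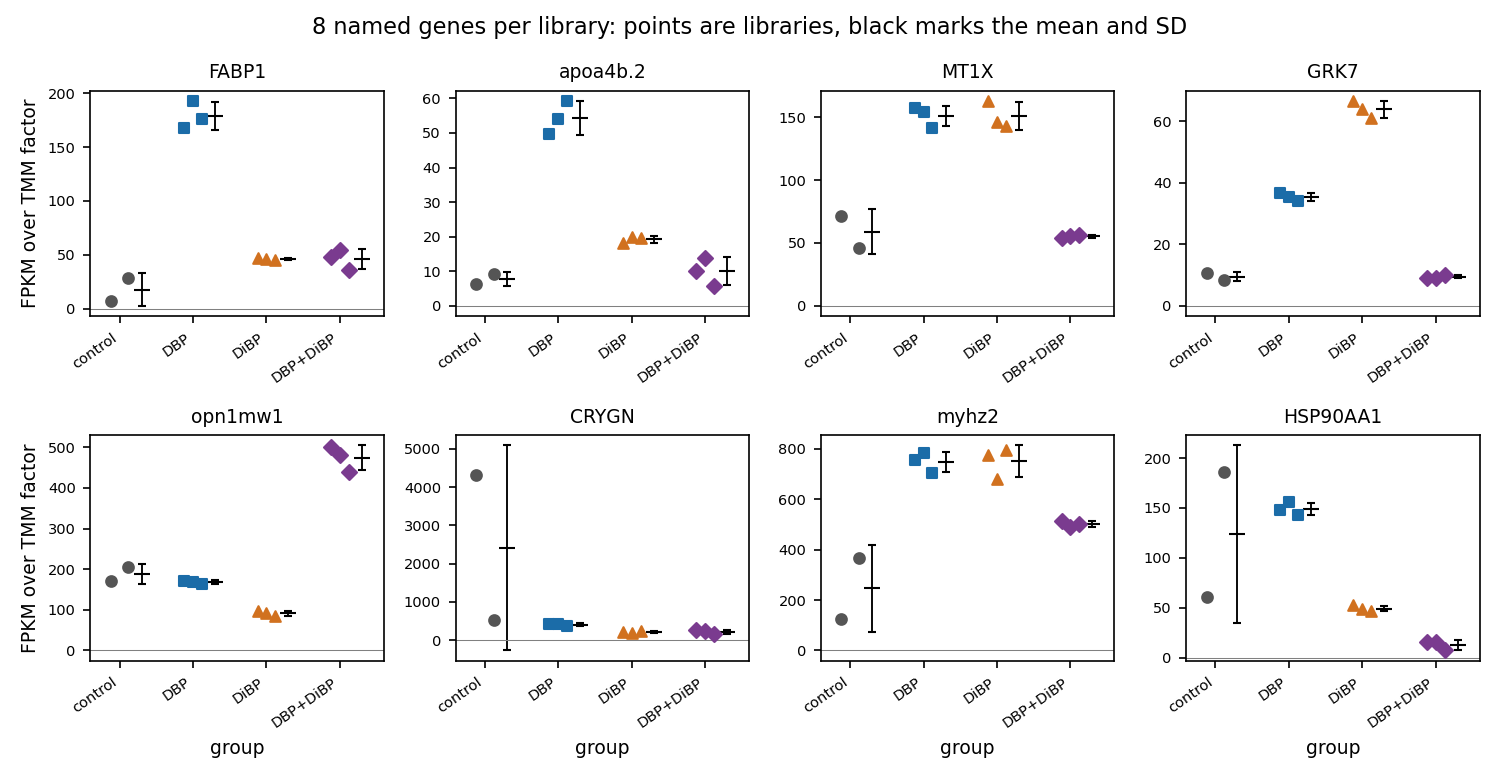
FPKM divided by the TMM factor for 8 genes in the 11 libraries, with points for libraries and black marks for the group mean and standard deviation. FABP1 averages 179 in DBP against 17.8 in the controls, and HSP90AA1 averages 13.1 in the combined exposure against 124.

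Genes called in all comparisons with control. In all 3 comparisons 123 genes were higher and 74 lower. Among those higher, with changes for DBP, were MSH4 (ENSDARG00000075826, 2.66 ± 0.22), a meiotic gene, and B3GNT5 (ENSDARG00000004396, 1.96 ± 0.32), of glycolipid synthesis. ECRG4 (ENSDARG00000088717, 1.99 ± 0.23), adgrg4b (ENSDARG00000094386, 1.65 ± 0.17) and the visual cycle isomerase RPE65 (ENSDARG00000007480, 1.22 ± 0.13) were others. MGST2 (ENSDARG00000071345, 1.32 ± 0.17), a glutathione transferase, was higher too, whereas GPI (ENSDARG00000012987, -0.68 ± 0.09), an enzyme of glycolysis, was lower. Changes in the same order for DiBP were MSH4 (2.59 ± 0.22), B3GNT5 (2.97 ± 0.32), ECRG4 (1.76 ± 0.23), adgrg4b (2.78 ± 0.17), RPE65 (0.91 ± 0.13), MGST2 (2.3 ± 0.17) and GPI (-0.99 ± 0.09). For the combined exposure they were MSH4 (1.57 ± 0.22), B3GNT5 (1.99 ± 0.32), ECRG4 (1.38 ± 0.23), adgrg4b (1.70 ± 0.17), RPE65 (0.88 ± 0.13), MGST2 (1.14 ± 0.17) and GPI (-0.76 ± 0.09).

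DBP and DiBP shared 1397 higher and 684 lower genes, and 24 went opposite ways. Independent draws would give 296 and 150.7 (n1n2/N). All comparisons used the same 2 controls, so part of the excess may come from the shared controls: in simulations of unchanged groups with shared controls the median overlap was 0 and the highest 4507 and 4929. Shares of genes with the same sign were 76.5% (DBP and DiBP), 64.8% (DBP and both) and 69.9% (DiBP and both), at or below the simulated 76.6%, 74% and 74.9%. The covariance of the DBP and DiBP changes was 0.267, and the simulated covariance 0.115 (SD 0.133). For DBP and the combined exposure the overlap was 137 higher and 91 lower against 32.9 and 18.2 (simulated median 0 for both), with 31 opposite and a covariance of 0.118 against a simulated 0.115. For DiBP and the combined exposure it was 196 and 174 against 54.1 and 46.1 (simulated median 0 for both), with 65 opposite and a covariance of 0.175 against 0.115. For genes called in all 3, the simulated median was 0 and the highest 4250 higher and 4701 lower. The 197 genes shared by all 3 became 150 without control library 1, 2821 without control library 2 and 324 without combined library 3.

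The isomers against each other. DBP and DiBP are constitutional isomers with n-butyl and isobutyl side chains, and their offspring differed in 2392 genes, 1195 higher and 1197 lower with DBP, with 3 libraries against 3. Whether the doses matched, or the larvae were collected at the same hour, was not given in the sources used here. Clock genes differed between the isomers: NR1D1 (-4.25 ± 0.75, adjusted p = 0.00414), PER1 (-2.67 ± 0.29, adjusted p = 2.10e-04), PER1 (-3.54 ± 0.48), ciarta (-2.88 ± 0.34) and CRY2 (-2.32 ± 0.14) were lower with DBP and cry3b (1.62 ± 0.09) was higher, and in the list 7 of 54 rose and 20 fell (8 and 26 over the list alone). The median was -0.58 (adjusted p = 2.68e-04, or 0.0535 with estimated correlation). Cell cycle genes were higher with DBP than with DiBP: 18 of 84 rose and 2 fell (23 and 4 over the list alone), with RRM2 (1.55 ± 0.12, adjusted p = 2.00e-05) and AURKB (0.72 ± 0.13) higher and the replication helicase MCM2 (ENSDARG00000102798, -0.81 ± 0.14) lower. The median was 0.32 (adjusted p = 1.93e-05, or 0.437 with estimated correlation). Cytochrome genes cyp2aa4 (3.07 ± 0.29, adjusted p = 7.33e-05) and cyp2aa11 (3.84 ± 0.28, adjusted p = 1.19e-05) and the glycoprotein gene cbln13 (4.05 ± 0.28, adjusted p = 6.87e-06) were higher with DBP than with DiBP, and nub1 (-5.28 ± 0.35) was lower.

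Digestive genes were higher with DBP. In the intestine list 7 of 37 rose and 1 fell (13 and 2 over the list alone), with apoa4b.1 (1.47 ± 0.14, adjusted p = 8.46e-05), apoa4b.2 (1.49 ± 0.24), FABP1 (1.95 ± 0.36) and DGAT2 (1.78 ± 0.25) of lipid handling. The median was 0.50 (adjusted p = 0.00558, or 0.901 with estimated correlation). That list was not called when genes under a mean CPM of 5 were left out (median -0.05, adjusted p = 0.433). In the exocrine pancreas list 6 of 22 rose and 0 fell (10 and 0 over the list alone), led by prss59.1 (1.17 ± 0.22). The median was 0.59 (adjusted p = 2.68e-04, or 0.915 with estimated correlation). The lipid synthesis genes FASN (-0.63 ± 0.08), ACACA (-0.63 ± 0.11) and the lipase LPL (-0.74 ± 0.08) were lower with DBP, though their list was not called, with 1 of 33 higher and 6 lower (3 and 9 over the list alone, adjusted p = 0.105) unless control library 1 or 2 was left out (adjusted p = 0.0476 and 0.0475). In the photoreceptor list 20 of 63 rose and 9 fell (26 and 11 over the list alone), with opn1mw1 (0.88 ± 0.10) higher and GRK7 (-0.85 ± 0.09) lower. The median was 0.32 (adjusted p = 0.00558, or 0.915 with estimated correlation). Leaving out control library 1 made the higher genes 14 in the intestine and 14 in the pancreas list, 26 in the lens and 12 in the ribosomal list. The stress sensor ern1 (1.42 ± 0.11, adjusted p = 1.30e-05) was higher with DBP. Lens genes (2 of 53 higher, 0 lower, 0 and 0 over the list alone, median 0.62, adjusted p = 0.0179, or 0.981 with estimated correlation) were not called without DBP library 2 (adjusted p = 0.0532) or combined library 3 (adjusted p = 0.055), nor ribosomal protein genes (0 of 83 higher, 0 lower, 0 and 0 over the list alone, median 0.16, adjusted p = 0.00558, or 0.981 with estimated correlation) without DBP library 2 (adjusted p = 0.0532) or DiBP library 2 (adjusted p = 0.0952).

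Of 10 named genes called in all comparisons with control, 6 differed between the isomers: adgrg4b (-1.13 ± 0.15), MGST2 (-0.98 ± 0.15), FOXQ1 (ENSDARG00000030896, -0.58 ± 0.10), SRL (-0.77 ± 0.16), B3GNT5 (-1.01 ± 0.29) and GPI (0.31 ± 0.08). For the other 4 and for 12 panel genes no difference passed. The 95% intervals for MT1X (-0.29 to 0.29), SOD1 (-0.24 to 0.20), MSH4 (-0.36 to 0.49) and ECRG4 (-0.22 to 0.67) held 0. So did those for CYP1A1 (-0.59 to 0.56), vtg1 (-0.47 to 0.63) and STAR (-0.06 to 0.85), called with neither isomer. Those for gpx1a (-0.56 to -0.11), il1b (-1.22 to -0.09), RPE65 (0.06 to 0.57) and SLC25A34 (ENSDARG00000087401, -0.84 to -0.04) left out 0. The skin list had a median of 0.02 (adjusted p = 0.798). The muscle list (-0.15, adjusted p = 0.322) was called lower with DBP without control library 1 or 2 (adjusted p = 0.0436 and 0.043). The count of 2392 genes fell to 1004 to 1301 without any 1 of the 6 libraries, rose to 4556 and 4592 without control libraries 1 and 2, and was 6869 with the 6 libraries fitted alone. With values scaled as deposited, the share higher with DBP was 39.1% in place of 50%.

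The combined exposure against each isomer. Combined offspring differed from DBP offspring in 3915 genes (1780 higher, 2135 lower) and from DiBP offspring in 4675 (2170 higher, 2505 lower), each with 3 libraries against 3. Heat shock genes were lower with both chemicals than with either. Against DBP 0 of 41 rose and 26 fell (2 and 27 over the list alone). The median was -0.77 (adjusted p = 1.55e-09, or 0.391 with estimated correlation). Against DiBP 0 of 41 rose and 19 fell (0 and 21 over the list alone). The median was -0.62 (adjusted p = 1.55e-07, or 0.43 with estimated correlation). HSP90AA1 (-3.58 ± 0.35, adjusted p = 6.04e-05) and HSPE1 (ENSDARG00000056167, -1.12 ± 0.11) show this against DBP, and HSPE1 (-1.04 ± 0.11) and HSPA9 (ENSDARG00000003035, -0.83 ± 0.09) against DiBP. hsp70l (-4.16 ± 0.97, adjusted p = 0.0111) and hsp70.1 (ENSDARG00000029688, -4.25 ± 0.94) were lower than in DBP offspring, and their changes were -2.54 and -2.73 without combined library 3. Immediate early genes were also lower. Against DBP 1 of 47 rose and 23 fell (1 and 25 over the list alone). The median was -0.38 (adjusted p = 1.71e-08, or 0.0781 with estimated correlation). Against DiBP 1 of 47 rose and 25 fell (1 and 25 over the list alone). The median was -0.42 (adjusted p = 1.55e-07, or 0.0896 with estimated correlation). NR4A1 (-0.97 ± 0.09) and BHLHE40 (-3.61 ± 0.13, adjusted p = 2.96e-08) are examples, with NR4A1 (-1.4 ± 0.09) and BHLHE40 (-4.02 ± 0.13, adjusted p = 4.04e-09) against DiBP.

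Intestine and exocrine pancreas genes were lower in combined than in DBP offspring. In the intestine list 0 of 37 rose and 23 fell (0 and 25 over the list alone), with apoa4b.2 (-2.51 ± 0.24, adjusted p = 5.70e-05) and apoa4b.1 (-1.56 ± 0.14). The median was -0.92 (adjusted p = 3.66e-11, or 0.101 with estimated correlation). In the exocrine pancreas list 0 of 22 rose and 16 fell (0 and 20 over the list alone). The median was -1.10 (adjusted p = 1.89e-09, or 0.282 with estimated correlation). Nuclear oxidative phosphorylation genes (2 of 82 higher, 30 lower, 3 and 41 over the list alone, median -0.29, adjusted p = 1.55e-09, or 0.443 with estimated correlation), ribosomal protein genes (0 of 83 higher, 32 lower, 0 and 53 over the list alone, median -0.42, adjusted p = 3.66e-11, or 0.662 with estimated correlation) and xenobiotic genes (1 of 32 higher, 17 lower, 1 and 18 over the list alone, median -0.52, adjusted p = 1.25e-05, or 0.209 with estimated correlation) were lower too, with cyp2n13 (-1.06 ± 0.12), cyp2p6 (ENSDARG00000042978, -1.08 ± 0.14) and cyp3c1 (ENSDARG00000015575, -0.62 ± 0.09) among the last. MT1X (-1.44 ± 0.13, adjusted p = 4.44e-05) and gpx4a (-0.66 ± 0.15) were lower, while the photoreceptor and pineal genes guca1aa (3.23 ± 0.28, adjusted p = 2.95e-05), aanat2 (2.80 ± 0.22, adjusted p = 1.31e-05) and GUCA1A (4.1 ± 0.54) were higher and GRK7 (-1.90 ± 0.09) and PDE6C (-1.86 ± 0.14) lower. Skin (0 of 39 higher, 9 lower, 0 and 10 over the list alone, median -0.41, adjusted p = 2.92e-04, or 0.744 with estimated correlation), muscle (0 of 65 higher, 3 lower, 0 and 1 over the list alone, median -0.43, adjusted p = 0.00948, or 0.825 with estimated correlation) and glucose (1 of 53 higher, 15 lower, 3 and 20 over the list alone, median -0.37, adjusted p = 0.00437, or 0.662 with estimated correlation) lists were lower as well. Lower genes without control library 1 were 39 (muscle), 22 (skin), 25 (glucose), 27 (lens), 50 (oxidative phosphorylation) and 74 (ribosomal). The lens list (0 of 53 higher, 3 lower, 0 and 0 over the list alone, median -0.53, adjusted p = 0.0146, or 0.825 with estimated correlation) was not called without combined library 3 (adjusted p = 0.323). The p53 and apoptosis list (3 of 46 higher, 11 lower, 4 and 12 over the list alone, median -0.12, adjusted p = 0.0348, or 0.443 with estimated correlation) was not called without that library (adjusted p = 0.176), nor with values as deposited (median 0.04, adjusted p = 0.0623).

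Against DiBP, cell cycle genes were higher in combined offspring: 37 of 84 rose and 8 fell (46 and 9 over the list alone), with TOP2A (1.38 ± 0.16), RRM2 (1.08 ± 0.12) and CCNA2 (1.07 ± 0.14). The median was 0.46 (adjusted p = 6.13e-05, or 0.237 with estimated correlation). In the photoreceptor list 30 of 63 rose and 11 fell (31 and 13 over the list alone), with opn1mw1 (2.38 ± 0.10, adjusted p = 2.34e-08) and LRAT (3.91 ± 0.31, adjusted p = 5.91e-06) higher and GRK7 (-2.74 ± 0.09, adjusted p = 8.00e-09) lower. The median was 0.42 (adjusted p = 1.52e-04, or 0.43 with estimated correlation). Clock genes split, with bmal2 (ENSDARG00000041381, 3.27 ± 0.18, adjusted p = 3.15e-07) higher and PER1 (-4.86 ± 0.29, adjusted p = 6.74e-07) and PER3 (-3.45 ± 0.15) lower, and in the list 13 of 54 rose and 25 fell (14 and 26 over the list alone). The median was -0.48 (adjusted p = 0.05, or 0.237 with estimated correlation). That p was just under the threshold before rounding. The call was lost without control libraries 1 or 2 (adjusted p = 0.0902 and 0.0849), DBP libraries 1, 2 or 3 (0.056, 0.0518 and 0.0522), DiBP library 2 (0.0614) or combined library 3 (median -0.05, adjusted p = 0.0692). Glucose and fasting genes (1 of 53 higher, 23 lower, 1 and 23 over the list alone, median -0.43, adjusted p = 1.52e-04, or 0.43 with estimated correlation), antioxidant genes (1 of 35 higher, 16 lower, 1 and 18 over the list alone, median -0.34, adjusted p = 1.88e-04, or 0.146 with estimated correlation), intestine genes (0 of 37 higher, 15 lower, 1 and 16 over the list alone, median -0.51, adjusted p = 2.28e-04, or 0.303 with estimated correlation), oxidative phosphorylation genes (2 of 82 higher, 15 lower, 2 and 15 over the list alone, median -0.22, adjusted p = 3.45e-05, or 0.597 with estimated correlation), muscle genes (1 of 65 higher, 11 lower, 1 and 10 over the list alone, median -0.58, adjusted p = 4.18e-04, or 0.709 with estimated correlation) and skin genes (0 of 39 higher, 8 lower, 0 and 8 over the list alone, median -0.47, adjusted p = 7.74e-04, or 0.669 with estimated correlation) were lower. MT1X (-1.44 ± 0.13, adjusted p = 1.95e-05), ANPEP (-1.64 ± 0.21) and FASN (-0.68 ± 0.08) are examples. Lower genes without control library 1 were 47 (muscle), 41 (oxidative phosphorylation), 23 (skin) and 12 (exocrine pancreas). Inflammation and complement genes (2 of 49 higher, 12 lower, 2 and 12 over the list alone, median -0.22, adjusted p = 0.00816, or 0.146 with estimated correlation) were lower with SOCS3 (-1.11 ± 0.07) and nfkbiaa (-1.33 ± 0.12). The exocrine pancreas list (0 of 22 higher, 5 lower, 0 and 5 over the list alone, median -0.46, adjusted p = 0.00601, or 0.662 with estimated correlation) was not called without combined library 3 (adjusted p = 0.0724).

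The count against DBP rose to 6173 and 6187 without control libraries 1 and 2, and fell to 2327, 2218, 2573, 2562 and 2562 without DBP libraries 1, 2 and 3 and combined libraries 1 and 2. Against DiBP the count fell to 2947 without DiBP library 3 and stayed within 1.5 times without any other single library. With values scaled as deposited, 74% of the genes that differed from DBP and 64.4% of those that differed from DiBP were higher, in place of 45.5% and 46.4%.

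The combined exposure against the sum of the single exposures. On the log2 scale, the change with both chemicals departed from the sum of DBP and DiBP changes in 6626 genes. Above it (rise) lay 3015, below it (fall) 3611. Intestine, oxidative phosphorylation and muscle genes, higher with each single exposure, fell. Low levels in the shared controls would give both. In the intestine list 0 of 37 rose and 27 fell (0 and 27 over the list alone), with apoa4b.2 (-3.84 ± 0.36) and mep1a.1 (-2.97 ± 0.23). The median was -2.0 (adjusted p = 6.01e-11, or 0.116 with estimated correlation). In the oxidative phosphorylation list 1 of 82 rose and 60 fell (1 and 63 over the list alone), with NDUFA10 (-1.25 ± 0.13). The median was -0.68 (adjusted p = 9.02e-13, or 0.308 with estimated correlation). In the muscle list 0 of 65 rose and 47 fell (1 and 49 over the list alone). The median was -1.79 (adjusted p = 2.07e-09, or 0.457 with estimated correlation). It was -0.85 without control library 1. MT1X (-2.83 ± 0.20, adjusted p = 2.59e-06), GRK7 (-4.64 ± 0.14, adjusted p = 2.86e-09), GADD45B (-2.22 ± 0.13) and SOCS3 (-2.08 ± 0.11) lay below the sum, and so did the clock genes PER1 (-7.19 ± 0.43, adjusted p = 7.59e-07) and BHLHE40 (-5.65 ± 0.19, adjusted p = 5.99e-09).

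Cell cycle genes lay above the sum: 47 of 84 rose and 6 fell (48 and 7 over the list alone), with TOP2A (2.38 ± 0.25), CDK1 (ENSDARG00000087554, 2.63 ± 0.31) and plk1 (ENSDARG00000058471, 1.88 ± 0.23). The median was 0.84 (adjusted p = 7.24e-07, or 0.116 with estimated correlation). GUCA1A (7.36 ± 0.80, adjusted p = 5.21e-05), LRAT (5.46 ± 0.47) and bmal2 (4.06 ± 0.26) were also above it. The lens list (9 of 53 higher, 0 lower, 0 and 0 over the list alone, median 1.4, adjusted p = 5.30e-04, or 0.642 with estimated correlation) had a median of 0.09 without control library 1 (adjusted p = 0.426) and 2.75 without control library 2, and 32 of 100 simulations of unchanged groups gave as large a median. Skin (0 of 39 higher, 28 lower, 0 and 28 over the list alone, median -1.24, adjusted p = 9.94e-09, or 0.415 with estimated correlation), exocrine pancreas (0 of 22 higher, 18 lower, 0 and 19 over the list alone, median -1.62, adjusted p = 1.34e-06, or 0.379 with estimated correlation), ribosomal (0 of 83 higher, 38 lower, 0 and 60 over the list alone, median -0.63, adjusted p = 6.94e-09, or 0.488 with estimated correlation) and glucose (4 of 53 higher, 28 lower, 5 and 29 over the list alone, median -0.98, adjusted p = 1.44e-04, or 0.398 with estimated correlation) lists lay below the sum, with medians of -0.80, -1.01, -0.35 and -0.64 without control library 1. Heat shock (0 of 41 higher, 19 lower, 1 and 20 over the list alone, median -0.97, adjusted p = 4.20e-05, or 0.457 with estimated correlation) and immediate early (2 of 47 higher, 22 lower, 4 and 22 over the list alone, median -0.54, adjusted p = 1.21e-04, or 0.116 with estimated correlation) lists lay below it too, and the heat shock median was -0.57 without control library 1. With values scaled as deposited 63.4% of the genes were above the sum in place of 45.5%. Since doses were not given, the sum is a reference and not a prediction for any dose.

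**Figure D5:**
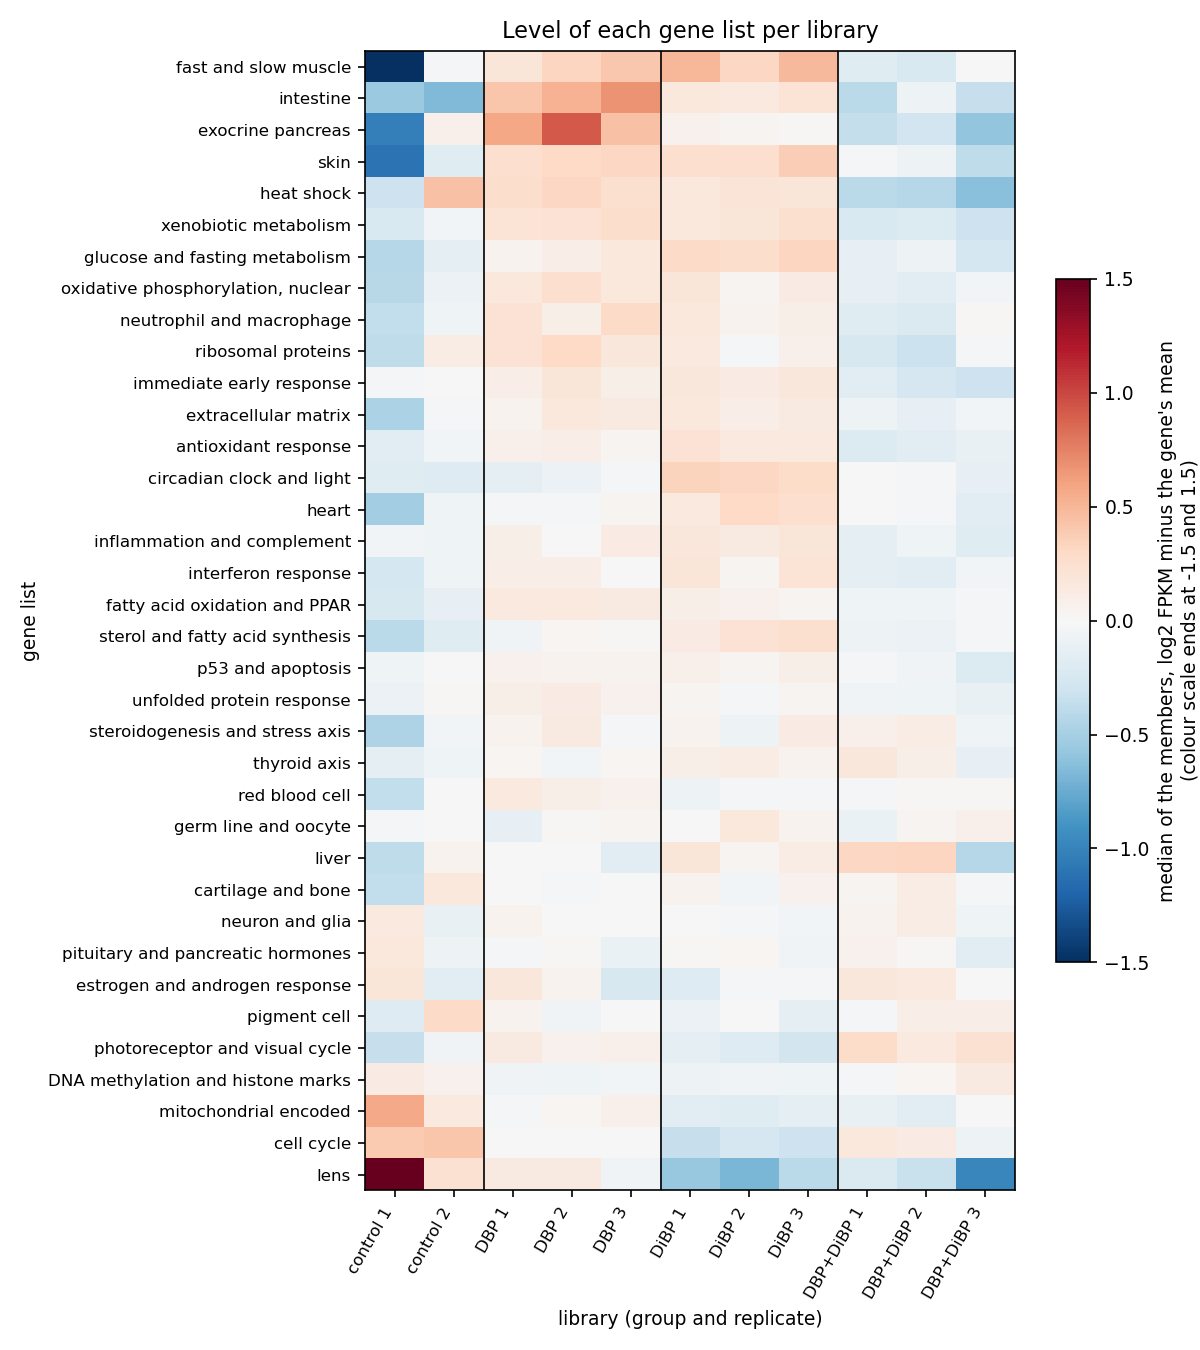
Heat map of 36 gene lists (vertical) in the 11 libraries (horizontal), with color for the median over a list's genes of log2 level minus the gene's mean, on a scale from -1.5 to 1.5. Intestine genes are highest in the DBP libraries, cell cycle genes lowest in the DiBP libraries, and lens genes highest in control library 1.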

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

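The tests of explanations in this part were all chosen only after the results were seen.

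The interaction was marked for a closer look because the difference between groups was tested: 6626 genes departed from the sum of the single responses, with 5269 to 8647 when single libraries were left out. In 5 of 100 simulations unchanged groups gave as many (highest 7670).

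Clock genes differed from control with DiBP (11 of 11 morning genes higher, 5 of 8 evening genes lower) and DBP (3 and 3). The morning minus the evening median was 3.9 for DiBP and 1.77 for DBP. Freezing of the larvae at different clock phases would give this. For DiBP the tables argue against 1 control library alone as the source, because the value was at least 4.14 when either was left out. Parental exposure setting the clock state could not be told apart from time of collection, since the combined libraries themselves spanned 2.57 and collection times were not given in the sources used here. What stays open is whether larvae frozen at the same hour would differ.

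Muscle, skin, lens and exocrine pancreas lists differed from control, and control library 1 stood apart in them. For DBP and DiBP, 8 of 8 medians fell to under 0.5 of their size without it, and in 7 of 8, 5 or more of 100 simulations of unchanged groups gave as large a median. Control library 1 alone and a chance difference between the libraries still cannot be told apart from an effect of exposure, because the lists were picked for the extreme levels of that library, which favors both outcomes. In the intestine and cell cycle lists, also picked after the results, 0 of 4 medians fell as far without that library. What stays open is whether the exposures changed muscle, skin, lens or pancreas genes, because 2 control libraries cannot show which is typical.

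Few genes passed the test between the combined exposure and the controls. The tables argue against spread from combined library 3 alone. With it out and 2 libraries per group, 9 of 9 fits gave the combined exposure under 0.5 times each single-exposure count. Counts were 246 to 307 (1089 with only library 3 out) against 1333 to 1581 for DBP. The spread between the control libraries hiding changes cannot be told apart from smaller changes: the median absolute change was 0.224 against 0.279 for DBP and 0.365 for DiBP, but the count rose to 2898 with both apart libraries left out. Clock phase cannot be told apart either, with the combined group 0.64 from control through library 3 (0.45), while libraries 1 and 2 (-2.12 and -1.92) lay near the controls (-1.93 and -1.73). Whether both chemicals together act less than each alone is possibly a matter of dose, and stays untested.

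Regrouping was run only for comparisons of 3 against 3, which makes 10 splits, too few for a share under 0.05. The real split gave 2392, 3915 and 4675 genes for DBP against DiBP and the combined exposure against each, in 1 of 10 splits each time (DBP against DiBP 1 of 10, combined against DBP 1 of 10, combined against DiBP 1 of 10), and the highest other was 0.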

How the results depend on the processing

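Calls against control rest on 2 control libraries that differ more than any other pair, and the cause was not tested. When either control is left out, the lone control is assumed to vary like the other groups. At 13396589 to 15381114 reads, small changes were mostly missed: on simulated data 20.9% of 1.5-fold changes were called for DBP against control. The planned count tests (edgeR as the main test, DESeq2 as an alternative) were not run, since the files hold FPKM. With replicate number as a block, counts moved by over 1.5 times only for the combined exposure against control (392) and the overlap (113), and the pairing check gave no ground for pairs. Direction never reversed for a called named gene.

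Genes changed (DBP, DiBP and combined against control, then DBP against DiBP, combined against DBP, combined against DiBP, interaction) were 2946, 5807, 671, 2392, 3915, 4675 and 6626. At 2-fold or more they were 1074, 1975, 267, 694, 1029, 1184 and 3522, with an overlap of all comparisons with control of 61 in place of 197. With only the groups compared they were 912, 3430, 0 (limma; 1985 at an unadjusted p under 0.05), 6869, 5053 and 5906. Values as deposited, other pseudocounts, voom and leaving out both apart libraries were chosen after seeing the data. With both apart libraries out they were 4459, 5922, 2898, 7154, 7867, 8058 and 8076, with an overlap of 742. Without the filter the combined exposure against control gave 408 and the overlap 118. RLE, as-deposited, voom and CPM settings stayed within 1.5 times of each count of genes changed.

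With each library left out in turn, counts ran from 1556 to 6061 (DBP), 3562 to 8599 (DiBP), 243 to 4654 (combined), 1004 to 4592 (DBP against DiBP), 2218 to 6187 and 2947 to 6738 (combined against DBP and DiBP) and 5269 to 8647 (interaction), and the overlap from 62 to 2821. Lists called numbered 106 of 252, with 102 to 121 when single libraries were left out. Called members moved by over 1.5 times without control library 1 in 10 of 18 (DBP), 5 of 17 (DiBP) and 5 of 12 (combined) called lists, and without control library 2 in 9, 5 and 9. Without either one they moved in 4 of 7 (DBP against DiBP), 8 of 16 (combined against DBP) and 6 of 17 (combined against DiBP), and for the interaction in 0 and 4 of 19. With an estimated correlation 0 of 252 were called (camera in limma; 40 at an unadjusted p under 0.05, lowest adjusted p = 0.0535).

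List tests that reversed direction and were called before or after, with the cause not tested, had these medians. Without control library 1: cartilage and bone in DBP -0.264 (adjusted p = 0.00725 in limma), exocrine pancreas in DiBP -0.037, ribosomal in DiBP -0.049, and in the combined exposure muscle -0.049 and glucose -0.143. Without control library 2: exocrine pancreas 0.575 and ribosomal 0.216 in the combined exposure. With both apart libraries out: neuron and glia in DBP 0.099, cartilage and bone in DBP -0.264 and in DiBP -0.18, and in DiBP exocrine pancreas -0.038, heat shock -0.251 and ribosomal -0.05. In the combined exposure muscle was -0.191 and oxidative phosphorylation -0.027, and lens against DiBP 0.218. Other medians changed sign too, such as exocrine pancreas in the combined exposure, called as -0.478 without control library 1 (adjusted p = 1.02e-06). Ranges over single libraries left out were -0.264 to 0.351 and -0.179 to 0.449 (cartilage and bone, DBP and DiBP), -0.037 to 1.051 and -0.478 to 0.575 (exocrine pancreas, DiBP and combined), -0.049 to 1.64 (muscle, combined), -0.143 to 0.278 (glucose, combined), -0.25 to 0.482 (heat shock, DiBP), -0.167 to 0.218 (lens, combined against DiBP), -0.119 to 0.1 (neuron and glia, DBP), -0.003 to 0.297 (oxidative phosphorylation, combined), and -0.049 to 0.49 and -0.32 to 0.216 (ribosomal, DiBP and combined). With values as deposited no called list test changed direction, but the medians of the p53 list (combined against DBP, 0.042) and the fatty acid oxidation list (combined against DiBP, 0.003) did, and both calls were lost.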

Other observations

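Lists not described above did not pass the list test against control as a whole, but held called genes. In the interferon list 3 of 22 rose and 1 fell with DBP (3 and 1 adjusted over the list alone, adjusted p = 0.276 in limma), with ifi27.1 (ENSDARG00000017489, 2.28 ± 0.41) and ifi27.2 (ENSDARG00000039243, 2.2 ± 0.46) higher and ifi44a1 (ENSDARG00000029720, -1.74 ± 0.28) lower. The antiviral GTPase mxc (ENSDARG00000024789, 2.12 ± 0.38) rose with DiBP, and mxc (2.33 ± 0.38) rose with both. The glial glutamate transporter SLC1A2 (ENSDARG00000052138, 1.2 ± 0.13, adjusted p = 1.81e-04) rose with DBP, and with DiBP the change was 2.04 ± 0.13, and the neurogenic factor NEUROD1 (ENSDARG00000019566, -1.70 ± 0.31) fell, in a list of neuron and glia genes where 3 of 78 rose and 1 fell with DBP (3 and 1 adjusted over the list alone). Its median (-0.03) and mean (0.04) differed in sign (adjusted p = 0.928). Of the unfolded protein list, DDIT4 (ENSDARG00000037618, 0.63 ± 0.12) and dnajc3a (ENSDARG00000041110, 0.65 ± 0.16) rose with DBP, where 5 of 46 genes of the list rose and 0 fell (4 and 0 adjusted over the list alone, adjusted p = 0.137), and the chaperone HSPA5 (ENSDARG00000103846, -0.86 ± 0.18) fell with both.

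The embryonic globins HBE1 (ENSDARG00000045143, 1.77 ± 0.20) and hbae3 (ENSDARG00000079305, 1.06 ± 0.17) rose with DBP among 25 red blood cell genes, 4 higher and 0 lower (6 and 1 adjusted over the list alone, adjusted p = 0.137), while alas2 (ENSDARG00000038643, -0.84 ± 0.21), the first enzyme of heme synthesis there, fell with DiBP. The steroid reductase genes SRD5A2 (ENSDARG00000043587, 0.95 ± 0.16) and SRD5A2 (ENSDARG00000039067, 1.56 ± 0.41) rose with DiBP, with 4 of 19 steroid and stress genes higher and 0 lower (3 and 0 adjusted over the list alone, adjusted p = 0.319). The cartilage factor SOX9 (ENSDARG00000043923, -0.62 ± 0.12) fell with DiBP and PHEX (ENSDARG00000062363, 0.48 ± 0.13) rose (2 of 34 cartilage and bone genes higher and 1 lower, the same counts adjusted over the list alone, adjusted p = 0.507, but 0.005 without control library 2).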
